A study of Mus musculus with 31 samples.

How the data were processed

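The labels describe 31 single-nucleus RNA libraries of the dorsal hippocampus from pilocarpine-treated and saline-treated littermates, made with the Chromium 3' v3 kit from frozen tissue after at least 12 hours without seizures on EEG. Libraries were grouped by the treatment and time labels into epilepsy at 3 weeks (n = 8), control at 3 weeks (n = 7), epilepsy at 6 weeks (n = 8) and control at 6 weeks (n = 8), and carried 1 of 8 batch labels, 4 per time. Batches are nested in the times, so the times themselves were not compared, only the treatment effects within them.

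The deposited count matrix holds UMI counts per gene and nucleus as whole numbers. Per the readme, the authors aligned reads with Cell Ranger 7.1.0, removed ambient RNA with SoupX 1.6.2 and rounded the result to integers, kept the singlets of scDblFinder 1.22.0, and merged the nuclei in Seurat 5.3.0. The readme names the build GRCm39 and the submitters' processing notes both GRCm39 and mm10, so no coordinates are given. Totals, genes and percent of mitochondrial UMIs recomputed from the matrix equalled the authors' deposited metadata for all 152,274 nuclei (tolerance 1e-06 for the percent). The readme states filters of more than 200 genes, more than 500 UMIs and under 5% mitochondrial UMIs; the files held 139 nuclei with at most 200 genes and 2362 with at most 500 UMIs, 149,777 nuclei passed the stated filter, and all were kept. Rounding after ambient removal sets many low counts to 0, and part of the ambient RNA can remain, so transcripts of other cells were measured in each class. No doublet caller was run on these singlets, but doublets can remain: 11 unnamed clusters (2587 nuclei) had at least 3 detected markers of 2 classes, and 5 of them (394 nuclei) all markers of both. The named mossy cell cluster (243 nuclei) also had 4 of 6 markers of CA3 neurons. The authors' cell annotation was not used, so classes were rebuilt and may differ from the study's.

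Counts of each nucleus were scaled to 10,000, log-transformed and reduced to 30 principal components over 2000 variable genes seen in at least 100 nuclei, with scores clipped at 10 and genes chosen in 20 bins of mean expression. A graph of 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1.5 and seed 1 into 60 clusters. A cluster took a class name only with at least 3 detected markers of it from a fixed list and none of the contrary signs set out in advance. Markers counted as detected in a share of nuclei of 0.1 and at 2-fold over the other nuclei with 10 CPM added. The 10 leading genes by fold, which also needed 20 CPM, could hold no more markers of another class than of the cluster's own. By this rule 29 clusters were named; in cluster 2 (12,652 nuclei of CA1) and cluster 37 (503 GABAergic nuclei) the leading genes held 0 markers of any class, and their names rest on detected markers alone. Nuclei of the 31 unnamed clusters made up 8.65% to 93.5% of a library, and control_3wk replicate 5, with 93.5% and a median of 698 UMIs, was left out in an alternative. Clustering was repeated without Tdo2, Dsp, Rfx3, Calb1, Wfs1, Gpc5 and Aqp4, markers that differed between the groups within their own class; 99.2% of nuclei kept their class. Those genes are not reported as single results of their classes, but they stay in the gene lists that hold them.

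For each class, counts were summed per library with at least 10 nuclei of the class and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with batch as a covariate and a treatment coefficient per time. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in the class. The difference of the coefficients tested whether the effect differed between 6 and 3 weeks. Standard errors are the size of the log2 fold change divided by the square root of F. Where a group held 1 to 3 UMIs of a called gene in all, the ratio of counts with an exact 95% interval replaces the fitted fold; it covers counting error only. Levels are summed counts divided by the UMIs of the class (CPM). Shares of nuclei were compared by an exact two-sided permutation test within batches on logit shares, adjusted over 16 classes and both times. Gene lists (32 in all: pathways, cell identity, mitochondrial transcripts and transcripts of other cells) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, where at least 5 members were measured; the adjustment ran over the lists of a class and time. In 20 pairs of class and list fewer than 5 members were measured and no test was made.

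Groups, main tests, gene lists, naming markers and the rule for named genes were set before the data were examined. The rule took, per main class and time, genes with adjusted p under 0.05 and an absolute log2 fold change of at least 1, other than predicted gene models, and named the 5 smallest p in each direction for granule neurons, astrocytes and microglia and 3 for other classes, plus up to 4 members of each list with the smallest p. The gene tests of 15 classes, the list test and the share test were checked on counts simulated from the real means and library sizes. At a 2-fold change edgeR called from 70% of changed genes in microglia to 82.8% in granule neurons at 6 weeks among the main classes, and from 17.7% in microglia to 80.3% in CA1 at 3 weeks. For a 2-fold difference between the times it called 9.8% in microglia to 65.6% in granule neurons, and in the 7 other classes it called 3.2% to 82.3% over the 3 tests. Of simulated lists, 20 of 20 changed and 0 of 20 unchanged ones were called in each main class. Genes were drawn independently, so this does not check the list test for genes that vary together. The share test was simulated 200 times per class, with unadjusted p only. A logit shift of 1 gave p under 0.05 in a median over classes of 89.2% at 3 weeks and 99.8% at 6 weeks. The lowest was 35.5% (CA3 at 3 weeks), with 49.5% in microglia at 3 weeks. Without a shift the medians were 4.2% and 4.5%.

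Alternatives were DESeq2 1.42.0 (its dispersion fit was local in place of parametric for 2 glial classes), RLE size factors, no filter on low counts, no batch term, a minimum of 50 nuclei, the libraries of a time point alone, each batch left out, other denominators and no strata for the shares, and an estimated correlation for the lists. Chosen after seeing the data were the percent of mitochondrial UMIs of the class (log2, with 0.01 added) as a covariate, the fit without control_3wk replicate 5, granule neurons without cluster 19 or of cluster 0 alone, all nuclei as the denominator of shares, shares without epilepsy_3wk replicate 1 or epilepsy_6wk replicate 7, and the repeated clustering. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 did the remaining steps.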

Results

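The series measured gene expression in single nuclei of the dorsal hippocampus of male C57BL/6J mice. Treated animals had received pilocarpine, a muscarinic agonist that sets off a prolonged seizure (status epilepticus) and is used to model temporal lobe epilepsy, and control littermates had received saline. Tissue was taken 3 or 6 weeks later, and the design asks how each cell class differed between epilepsy and control at each time. Epilepsy had 8 libraries at each time and control had 7 at 3 weeks and 8 at 6 weeks. Each time had 4 batches, each with both treatments. The files held 152,274 nuclei and 33,696 genes, with 1596 to 10,484 nuclei and 10,572,004 to 48,049,403 UMIs per library. The median UMIs per nucleus of a library ranged from 698 to 6792 in control and 2221 to 7816 in epilepsy at 3 weeks, and from 2498 to 5654 in control and 1576 to 4926 in epilepsy at 6 weeks. Of 60 clusters, 29 were named from marker genes and fell into 16 classes with 113,448 nuclei, and 31 (38,826 nuclei) stayed unnamed. A class name below stands for granule-like, CA1-like and so on, since it rests on markers alone. The deposited metadata name each library after a mouse of its own, so the p-values measure the spread between animals. Fold changes below are log2 of epilepsy over control with their standard error, and levels are mean ± SD in CPM over the libraries of a group. A named gene moved the same way in 4 of 4 batches unless another number is given.

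At 6 weeks the epilepsy hippocampus held larger shares of oligodendrocyte and microglia nuclei and smaller shares of astrocyte and mossy cell nuclei than control. Oligodendrocytes, which form myelin, made up 20.4% ± 6.37 (SD, n = 8) of the nuclei in named classes against 10.0% ± 5.72 (n = 8) in control. Their share was higher in 4 of 4 batches (adjusted p = 0.0296, exact permutation test). Microglia, the resident immune cells, made up 5.85% ± 2.78 against 2.57% ± 2.02, also higher in 4 of 4 batches (adjusted p = 0.0247, exact permutation test). The astrocyte share was 8.15% ± 6.94 against 20.03% ± 9.69 and was higher in 0 of 4 batches, with the same exact adjusted p of 0.0247. Mossy cells, excitatory neurons of the dentate hilus, made up 0.048% ± 0.064 against 0.268% ± 0.205, from 12 nuclei in epilepsy and 86 in control (adjusted p = 0.0247, exact permutation test, higher in 0 of 4 batches). Without epilepsy_6wk replicate 7, at 0.188%, the epilepsy mean was 0.028% with the same exact adjusted p. At 3 weeks the share of immature granule neurons, the newborn neurons of the dentate gyrus, was higher in epilepsy at 2.04% ± 1.48 (n = 8) against 0.612% ± 0.255 (n = 7) in 4 of 4 batches (adjusted p = 0.0247, exact permutation test). The 3-week microglia share was 8.76% ± 12.0 against 1.15% ± 0.633 and did not pass (adjusted p = 0.084, exact permutation test); without epilepsy_3wk replicate 1, at 36.6%, the epilepsy mean was 4.79% (adjusted p = 0.0847, exact permutation test). Oligodendrocytes at 3 weeks, at 13.5% ± 6.29 against 7.81% ± 2.2, had the same exact adjusted p of 0.084. Without batch 41 both passed at 3 weeks (exact adjusted p = 0.0329 for each), as over all nuclei (0.0247 for microglia, 0.0123 for oligodendrocytes). Unnamed nuclei (mean 39.0% in control, 23.2% in epilepsy) lower the latter shares more in control. The two-sided tests used all reassignments within batches (648 at 3 weeks, 1296 at 6 weeks), adjusted over 32 class and time pairs. The smallest possible p was 0.0015. Without batches as strata none of the 5 calls held, with adjusted exact p from 0.063 to 0.146. The 6-week calls were lost with any 1 batch left out (exact adjusted p from 0.0593 to 0.0988). That of immature granule neurons was lost without batch 28, 29 or 40-3 (0.0988 to 0.115). Fewer reassignments raise the smallest possible p, so these losses need not reflect the batch. Clustering without the differing markers gave exact adjusted p = 0.0802 for immature granule neurons at 3 weeks. Shares of 1 library sum to 100%, so they do not move independently.

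**Figure D1:**
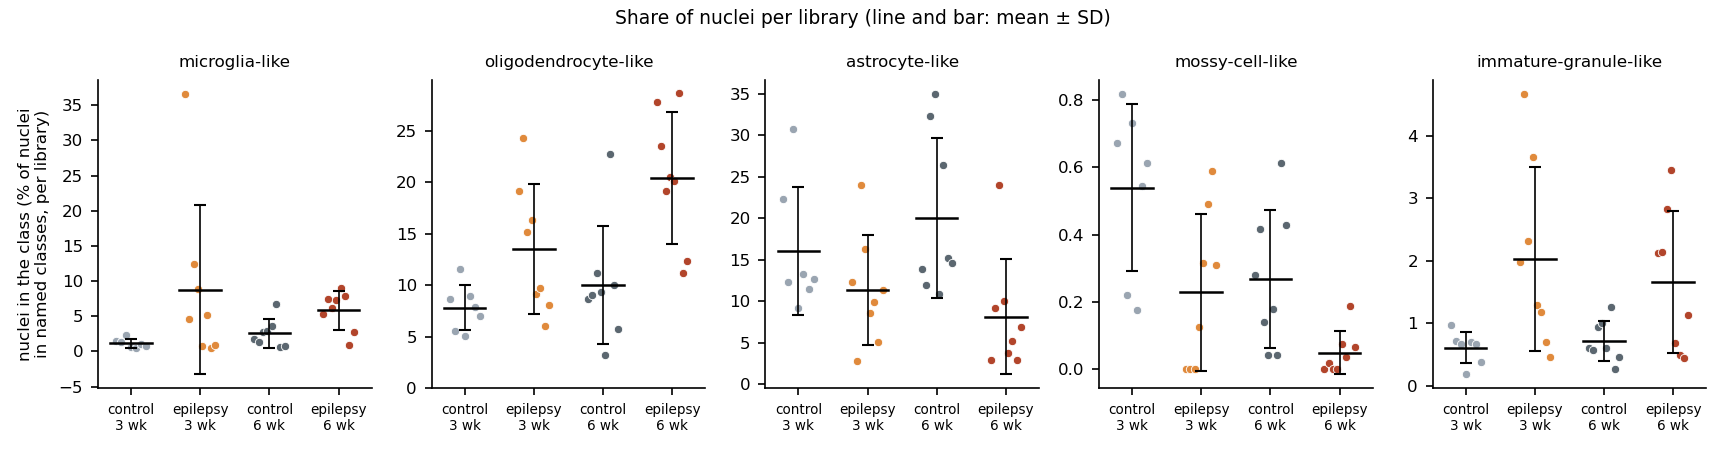
Percent of the nuclei in named classes that belonged to microglia, oligodendrocytes, astrocytes, mossy cells and immature granule neurons, with each library as a point and a line and bar for mean ± SD of control and epilepsy at 3 and 6 weeks. At 6 weeks oligodendrocytes averaged 20.4% in epilepsy against 10.0% in control.

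Granule neurons, the principal cells of the dentate gyrus, changed most genes among the 8 main classes. Expression of 1371 genes differed at 3 weeks (656 higher and 715 lower of 13,884 tested) and of 3142 at 6 weeks (1605 higher and 1537 lower). Col6a1, a collagen chain, rose from 3.41 ± 1.79 to 36.6 ± 7.49 CPM at 3 weeks (log2 fold change 3.23 ± 0.24, adjusted p = 1.35e-09) and from 3.44 ± 1.88 to 55.7 ± 30.7 CPM at 6 weeks (3.98 ± 0.21, adjusted p = 3.18e-13). Sema3e, a secreted guidance cue, rose from 14.7 ± 4.64 to 115 ± 61.5 CPM at 3 weeks and from 14.2 ± 6.53 to 115 ± 37.2 CPM at 6 weeks. Plcxd3, the diacylglycerol kinase Dgkb and the adhesion molecule Nectin3, which is also a naming marker of CA3 neurons, rose at 3 weeks by 2.70 ± 0.22, 1.38 ± 0.10 and 2.22 ± 0.20. The calcium-binding channel partner Kcnip3 rose from 102 ± 9.64 to 262 ± 31.9 CPM and Arhgap29, a Rho GTPase-activating protein, from 7.14 ± 1.44 to 30.3 ± 5.66 CPM at 6 weeks. The homeobox gene Mkx fell from 190 ± 22.4 to 88.1 ± 16.2 CPM at 3 weeks (−1.14 ± 0.11) and from 188 ± 25.1 to 73.8 ± 13.5 CPM at 6 weeks (−1.34 ± 0.10). Also lower at both times were the giant cadherin Fat4 (−1.36 ± 0.14 and −1.62 ± 0.13), the lipid kinase Pip5k1b (−1.19 ± 0.12 and −1.21 ± 0.12), Iqcm (−1.58 ± 0.15 and −1.18 ± 0.14) and Egfem1 (−1.14 ± 0.12 and −1.39 ± 0.12). Kitl, the ligand of the Kit receptor, fell from 32.8 ± 5.44 to 5.57 ± 1.98 CPM and Gfra2, the neurturin receptor, from 48.9 ± 19.2 to 12.6 ± 5.67 CPM at 6 weeks.

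Among the gene lists tested in granule neurons, genes of immature neurons were higher as a group at 3 weeks. Of 8 members measured, 5 rose and 1 fell over all genes, and 6 rose and 1 fell when adjusted over the list alone. Sox11 rose by 0.91 ± 0.14, Sox4 by 1.59 ± 0.26 and Igfbpl1 by 2.46 ± 0.69, and Prdm8 fell by 0.86 ± 0.16 on the log2 scale. The list holds Dcx, Sox11 and Igfbpl1, naming markers of immature granule neurons, whose share was 2.04% in epilepsy against 0.612% in control at 3 weeks. Sox11 was also a detected marker of cluster 19, of whose nuclei 96.1% came from epilepsy; without that cluster Sox11 stood at 0.89 and Igfbpl1 at 2.24. The list's median was 0.75 (camera adjusted p = 0.00403, and adjusted p = 0.0258 with an estimated correlation). At 6 weeks 3 rose, 1 fell and the list did not pass (adjusted p = 0.482). Granule identity genes had a median of −0.35 at 3 weeks and −0.21 at 6 weeks, with 5 of 14 lower at each time. That list passed with adjusted p = 0.00159 and 0.008, but not with an estimated correlation (adjusted p = 0.147 and 0.557). Of its 14 members 7 had served to name the class. Axon guidance genes moved both ways: 5 of 21 rose and 4 fell at 3 weeks, and 5 rose and 8 fell at 6 weeks, with no call for the list (adjusted p = 0.471 and 0.722). The repulsive cue Sema3a rose by 2.62 ± 0.25 and 2.76 ± 0.19 and the netrin receptor Unc5d by 1.37 ± 0.25 and 2.16 ± 0.23, and another netrin receptor, Dcc, fell by 0.59 ± 0.18 and by 1.30 ± 0.17.

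Genes of synaptic transmission and excitability also moved both ways in granule neurons, and none of their lists passed. Activity-regulated genes counted 2 higher and 1 lower of 14 at 3 weeks and 2 higher and 4 lower at 6 weeks (list adjusted p = 0.492 and 0.838). The pentraxin Nptx2 rose by 1.72 ± 0.33 and 1.72 ± 0.26, the neurotrophin Bdnf by 0.79 ± 0.24 (in 3 of 4 batches) and 1.19 ± 0.22. The nuclear receptor Nr4a3 fell by 1.63 ± 0.45 and 2.12 ± 0.38. Among 6 neuropeptide genes Penk, which encodes the enkephalin precursor, rose from 5.22 ± 4.15 to 30.7 ± 25.8 CPM at 3 weeks and from 6.28 ± 2.48 to 64.4 ± 37.3 CPM at 6 weeks (log2 fold change 3.23 ± 0.44, adjusted p = 7.24e-06). Transcripts of Cck, Sst and Vip, peptides of interneurons, fell at 6 weeks by 4.97 ± 0.82, 3.64 ± 0.87 and 3.11 ± 0.70, and the list did not pass at either time (adjusted p = 0.972 and 0.542). Of 19 glutamate receptor genes 3 rose and 3 fell at 3 weeks, and 8 rose and 3 fell at 6 weeks (adjusted p = 0.505 and 0.224). The kainate receptor subunit Grik3 fell from 54.2 ± 11.2 to 15.9 ± 6.22 CPM at 6 weeks and Grik4 rose from 180 ± 25.5 to 305 ± 39.8 CPM. Of 11 GABA-A receptor genes 1 rose and 4 fell at 3 weeks, and 4 rose and 3 fell at 6 weeks (adjusted p = 0.65 and 0.722), with Gabrg3 at −1.38 ± 0.18 and Gabrb2 at 0.49 ± 0.08 at 6 weeks. Potassium and HCN channel genes counted 2 higher and 4 lower of 22, then 6 higher and 3 lower (adjusted p = 0.65 and 0.86), with Kcnd2, which carries the A-type current, at −0.45 ± 0.08 and −0.48 ± 0.07. Sodium and calcium channel genes counted 0 higher and 1 lower of 19, then 2 higher and 3 lower (adjusted p = 0.263 and 0.628), with Cacna1i at −1.84 ± 0.27 at 6 weeks. Integrated stress response genes counted 1 higher of 8, then 2 lower (adjusted p = 0.505 and 0.162), among them the serine synthesis enzyme Phgdh at −2.18 ± 0.49 at 6 weeks.

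In the same granule libraries, mitochondrial transcripts had a median log2 fold change of −2.05 at 6 weeks (camera adjusted p = 0.0414, and adjusted p = 0.876 with an estimated correlation). Of 10 astrocyte transcripts 4 were lower (median −1.19, adjusted p = 0.008, and adjusted p = 0.557 with an estimated correlation). Oligodendrocyte transcripts had medians of 0.81 and −0.85 (adjusted p = 0.14 and 0.253) and microglia transcripts of 1.69 and −0.39 (adjusted p = 0.492 and 0.734). Over whole libraries, the percent of mitochondrial UMIs was 1.14% ± 0.791 in control and 0.533% ± 0.496 in epilepsy at 6 weeks, and 0.391% ± 0.339 and 0.424% ± 0.392 at 3 weeks. Different clusters held most of the class in control and epilepsy at 6 weeks: cluster 5 held 73.7% of granule nuclei in control and 11% in epilepsy, and cluster 0 held 23.5% and 84.7%; without epilepsy_6wk replicate 6 the share of cluster 5 in epilepsy was 3.4%. With cluster 0 alone 1454 genes were called at 6 weeks, 1368 of them among the 3142. At 3 weeks cluster 19 held 29.1% of granule nuclei in epilepsy and 1.1% in control, or 18.8% without epilepsy_3wk replicate 4 and 0.3% without control_3wk replicate 3. Without that cluster 1225 genes were called. Without the batch term in the model the counts were 766 and 1632, without batch 28 675 at 3 weeks and without batch 25 1623 at 6 weeks.

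**Figure D2:**
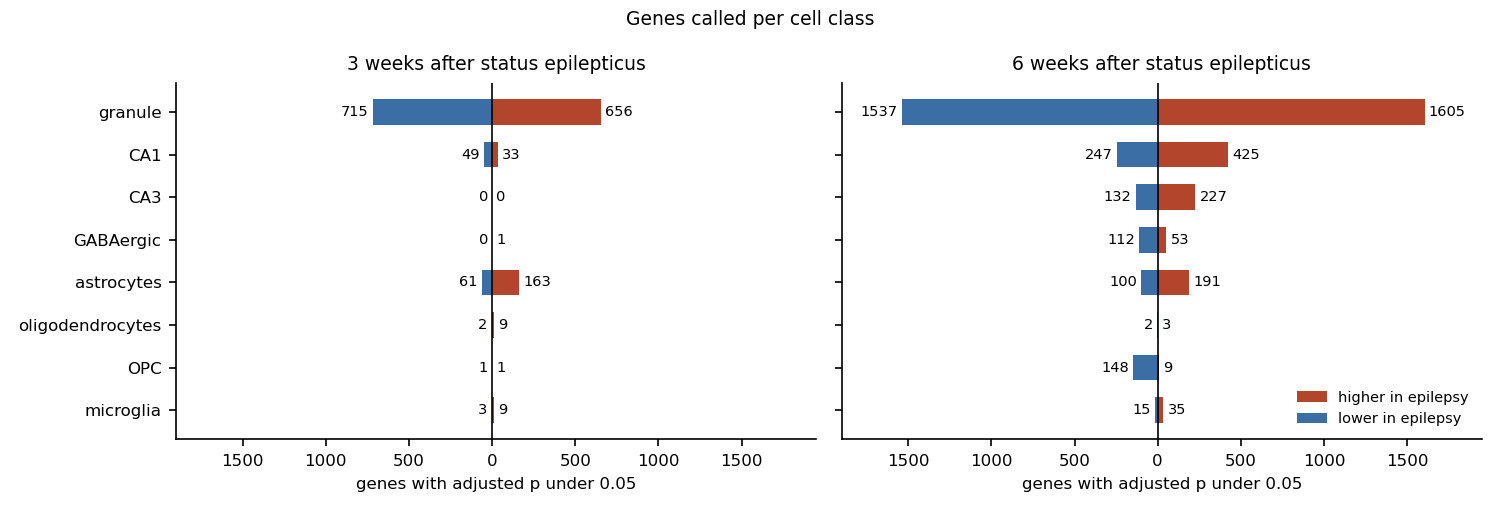
Number of genes called higher (bars to the right) and lower (bars to the left) in epilepsy than control in each of the 8 main cell classes at 3 and 6 weeks, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Granule neurons had 1371 and 3142 calls.

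**Figure D3:**
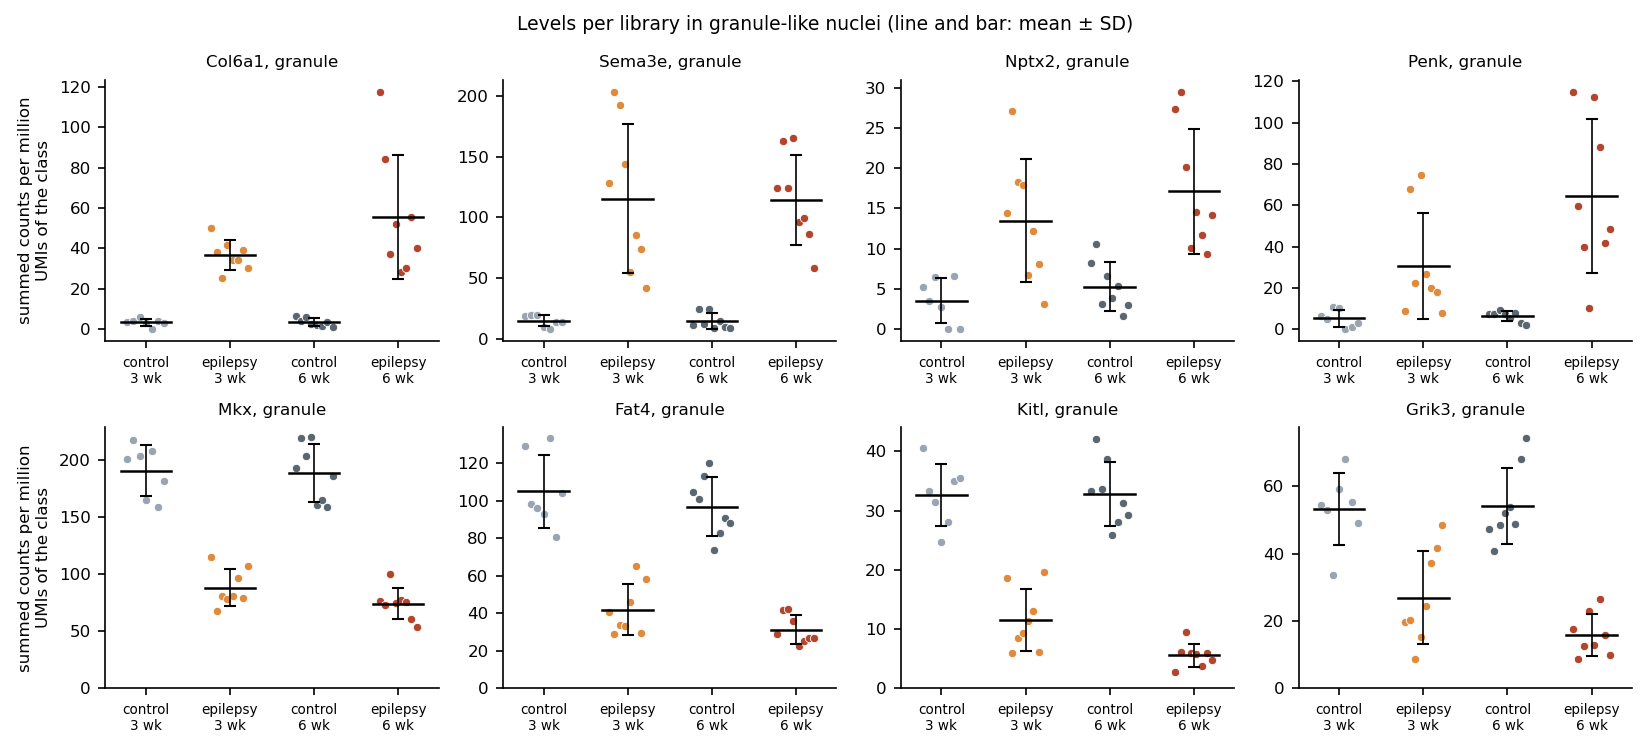
Level of 8 genes in granule neurons in CPM, with each library as a point and a line and bar for mean ± SD, for control and epilepsy at 3 and 6 weeks. Col6a1 averaged 36.6 CPM in epilepsy against 3.41 CPM in control at 3 weeks.

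In CA1 pyramidal neurons 82 genes differed at 3 weeks (33 higher and 49 lower of 14,129 tested) and 672 at 6 weeks (425 higher and 247 lower). Acvr1c, an activin receptor, rose from 1.87 ± 0.99 to 10.9 ± 4.16 CPM at 3 weeks (2.35 ± 0.32, adjusted p = 0.000326) and by 1.40 ± 0.27 at 6 weeks. Plekha2 rose from 1.14 ± 0.385 to 13.5 ± 5.28 CPM at 6 weeks (3.39 ± 0.32, adjusted p = 1.8e-07) and by 2.37 ± 0.42 in 3 of 4 batches at 3 weeks. Both genes are also among the 10 leading genes of cluster 0, which belongs to granule neurons, and granule transcripts had medians of 0.07 and 0.02 over 5 genes in CA1 (adjusted p = 0.912 and 0.931). The matrix proteins Edil3 and Smoc2 rose by 1.09 ± 0.15 and 1.14 ± 0.25 at 3 weeks and by 1.18 ± 0.14 and 1.69 ± 0.21 at 6 weeks. Car4, a membrane carbonic anhydrase, fell from 20.4 ± 5.73 to 7.30 ± 5.0 CPM at 3 weeks and from 17.7 ± 5.91 to 3.99 ± 1.2 CPM at 6 weeks. Fgf1, a fibroblast growth factor, fell by 1.57 ± 0.32 at 3 weeks, Ptges3l by 1.58 ± 0.32 at 3 weeks and 0.97 ± 0.29 at 6 weeks, and Tmtc2 by 1.07 ± 0.14 at 6 weeks. Scrg1 and the interneuron peptide Vip were higher in control at 6 weeks by ratios of 49.6 (95% interval 16.7 to 243) and 67 (18.3 to 558), from 3 and 2 UMIs over all epilepsy libraries.

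No list passed in CA1 at 3 weeks; the lowest adjusted p was 0.0601, for GABA-A receptors and for potassium and HCN channels (1 of 22 lower, Kcnip4 at −0.37 ± 0.09). At 6 weeks neuropeptide genes were lower as a group, with 2 of 5 lower over all genes and 3 adjusted over the list alone (median −2.45, adjusted p = 0.000713, and adjusted p = 0.167 with an estimated correlation). Activity-regulated genes (16 measured, median −0.23) and integrated stress response genes (1 of 8, Phgdh at −3.68 ± 0.68, median −0.28) each passed with adjusted p = 0.0483, and had adjusted p = 0.632 and 0.361 with an estimated correlation. The other neuronal lists did not pass at 6 weeks. Glutamate receptors had 1 of 17 called (Grik5 at 0.35 ± 0.08, adjusted p = 0.548 for the list), potassium and HCN channels 1 of 22 (Kcna1 at 0.47 ± 0.12, 0.412). Sodium and calcium channels had 1 of 19 called (Cacna2d3 at 0.20 ± 0.05, 0.577) and axon guidance 2 of 21 (Slit1 at 0.34 ± 0.07 and Robo2 at −0.30 ± 0.08, 0.412). Mitochondrial transcripts had a median of −4.69 (adjusted p = 2.37e-07), astrocyte transcripts of −2.26 with 5 of 10 lower and 1 higher (0.00857), and oligodendrocyte transcripts of −1.61 (0.0483). With an estimated correlation their adjusted p was 0.361, 0.397 and 0.632. Cluster 10 held 55.5% of CA1 nuclei in control and 5.8% in epilepsy at 6 weeks (1.5% without epilepsy_6wk replicate 6), and cluster 2 held 44.5% and 94.2%. With the mitochondrial covariate 85 genes were called at 6 weeks, 80 of them among the 672, and without control_3wk replicate 5 1036. DESeq2 with its own size factors gave 51.7% of 907 calls higher at 6 weeks, against 63.2% in the edgeR test, and 259 calls at 3 weeks; without the batch term the counts were 3 and 148, without batch 28 8 at 3 weeks and without batch 25 135 at 6 weeks.

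CA3 pyramidal neurons showed their calls at 6 weeks, when 227 genes were higher and 132 lower of 10,908 tested. Megf11, a receptor of the EGF-repeat family, rose from 15.2 ± 2.99 to 41.7 ± 14.7 CPM (1.54 ± 0.17, adjusted p = 2.61e-06). Hpgd, which inactivates prostaglandins, rose from 4.03 ± 3.07 to 27.4 ± 20.1 CPM and the adhesion molecule Sdk1 from 47.9 ± 24.6 to 101 ± 46.7 CPM. Slc6a1, the GABA transporter, fell from 10.1 ± 4.15 to 1.10 ± 1.19 CPM, and Pfdn5 and Qpct fell by 3.91 ± 0.63 and 3.66 ± 0.64 on the log2 scale. Of 22 potassium and HCN channel genes, the M-current subunit Kcnq3 fell from 728 ± 66.6 to 474 ± 79.1 CPM and Kcna1 rose by 0.40 ± 0.11 (list adjusted p = 0.957). Of 19 sodium and calcium channel genes 2 rose (Cacna1a by 0.30 ± 0.07, Cacna2d3 by 0.56 ± 0.14; list adjusted p = 0.149), and of 19 axon guidance genes 3 rose (Sema3e, Epha7 and Slit1; list adjusted p = 0.184). GABA-A receptor, glutamate receptor and activity-regulated lists did not pass at 6 weeks (adjusted p = 0.186, 0.0724 and 0.063). At 3 weeks edgeR called 0 genes, with 560 at an unadjusted p under 0.05, and DESeq2 called 1. The glutamate receptor list, which holds the CA3 naming marker Grik4, passed at 3 weeks with a median of −0.08 over 16 genes (adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). The activity-regulated, axon guidance, GABA-A receptor, potassium and sodium channel lists did not (adjusted p from 0.0916 to 0.39). At 6 weeks mitochondrial transcripts had a median of −3.01 (adjusted p = 1.29e-05) and oligodendrocyte transcripts of −1.52 with 2 of 10 lower (adjusted p = 3.63e-06), and these had adjusted p = 0.277 and 0.11 with an estimated correlation. Astrocyte transcripts had a median of −0.56 (adjusted p = 0.063). With the mitochondrial covariate 90 genes were called at 6 weeks, 82 of them among the 359. Without the batch term 28 were, and without batch 27 53. RLE size factors gave 50% of calls higher and DESeq2 45.4%, against 63.2% with TMM.

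GABAergic interneurons had 53 genes higher and 112 lower of 13,390 tested at 6 weeks. Col5a3, a collagen chain, rose from 1.21 ± 1.2 to 9.30 ± 5.03 CPM (2.56 ± 0.39, adjusted p = 0.000859). Oprk1, the kappa opioid receptor, rose from 7.90 ± 1.69 to 16.8 ± 5.54 CPM (1.06 ± 0.18, adjusted p = 0.00298) and the phospholipid flippase Atp8b1 by 1.33 ± 0.30. Ntng1, a netrin-like adhesion molecule, fell from 467 ± 134 to 211 ± 39.8 CPM and the GABA-A receptor subunit Gabra5 from 43.7 ± 7.47 to 25.1 ± 8.08 CPM. Scrg1 and the neurotensin receptor Ntsr2 fell by 4.72 ± 0.62 and 5.15 ± 0.76. The heat-shock gene Cryab was higher in control by a ratio of 69.2 (95% counting interval 23.4 to 338), from 240 UMIs against 3. RNA of other cells as their source was not tested. At 3 weeks Col5a3 was the 1 gene called, rising from 0.799 ± 0.604 to 7.12 ± 5.19 CPM (2.96 ± 0.47, adjusted p = 0.00819). Glutamate receptor genes were higher as a group at 6 weeks (18 measured, median 0.17, 5 higher when adjusted over the list alone, adjusted p = 0.000464, and adjusted p = 0.155 with an estimated correlation). No other neuronal list passed at 6 weeks. GABA-A receptors had 1 of 12 lower (adjusted p = 0.229), and neuropeptides, a list that holds the naming markers Sst and Vip, had Cck lower at −4.28 ± 0.79 among 9 (0.204). The others were potassium and HCN channels with Kcna1 higher and Kcnn2 lower of 22 (0.544), sodium and calcium channels with Cacna1a higher and Scn3b lower of 19 (0.688), and axon guidance (0.689). Extracellular matrix genes, with Tnr at 0.24 ± 0.06 and Sparc at −4.01 ± 0.82, did not pass either (0.623), nor did activity-regulated and stress response genes (0.287 and 0.351). Beside these, mitochondrial transcripts had a median of −2.58 and astrocyte transcripts of −1.64 with 3 of 8 lower (adjusted p = 4.29e-05 for each, and 0.591 and 0.155 with an estimated correlation). At 3 weeks oligodendrocyte transcripts were higher in all 10 members (median 1.30, adjusted p = 0.0108, and adjusted p = 0.822 with an estimated correlation). With the mitochondrial covariate 34 genes were called at 6 weeks, 27 of them among the 165. Without the batch term 7 were, and without batch 25 8. At 3 weeks edgeR called 0 genes without batch 28 (588 unadjusted) or 40-3 (940). Without control_3wk replicate 5 the count was 342, and DESeq2 called 10 genes at 3 weeks and 302 at 6 weeks.

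Astrocytes changed 224 genes at 3 weeks (163 higher and 61 lower of 10,800 tested) and 291 at 6 weeks (191 higher and 100 lower). Cd44, a hyaluronan receptor, rose from 11 ± 6.23 to 75.5 ± 66.2 CPM at 3 weeks (2.81 ± 0.37, adjusted p = 6.47e-05) and from 8.52 ± 2.96 to 42.1 ± 19.8 CPM at 6 weeks (2.23 ± 0.34). Ddx60, an interferon-induced helicase, rose by 3.68 ± 0.47 in 3 of 4 batches at 3 weeks and by 2.20 ± 0.39 at 6 weeks, and the basement membrane collagen gene Col4a6 by 3.42 ± 0.51 and 3.41 ± 0.42. Pvt1, a long noncoding RNA, Car10, the prolyl hydroxylase subunit P4ha3 and the actin-severing protein Gsn were also higher at both times, by 2.28 ± 0.30, 1.89 ± 0.25, 2.97 ± 0.41 and 1.19 ± 0.25 at 3 weeks. At 3 weeks the channel partner Kcnip1 fell by 1.94 ± 0.39, Gpd1, which links glycolysis to lipid synthesis, by 1.47 ± 0.31, and the iron oxidase Heph by 1.16 ± 0.26. Also lower at 3 weeks were the glucocorticoid-induced gene Tsc22d3 by 1.04 ± 0.22 and Ranbp3l, also a naming marker of fibroblasts, by 1.10 ± 0.21. Igfbp2, which binds insulin-like growth factors, fell from 33.8 ± 14.5 to 14.4 ± 5.08 CPM at 6 weeks (−1.29 ± 0.17). Rell2, Vtn, Calb1 and the kinesin Kif21b stood at −3.58 ± 0.64, −2.44 ± 0.51, −2.35 ± 0.45 and −1.11 ± 0.22.

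Reactive astrocyte genes rose together in astrocytes at both times. Of 11 measured, 6 rose at 3 weeks and 5 at 6 weeks, and 10 and 8 when adjusted over the list alone, with medians of 1.51 and 1.39 (adjusted p = 3.46e-14 and 1e-11, and 0.0127 and 0.0217 with an estimated correlation). Osmr, the oncostatin M receptor, rose by 2.11 ± 0.43 and 1.99 ± 0.38, and Aspg by 3.24 ± 0.55 at 3 weeks. The list holds the naming marker Gfap. Interferon response genes were higher too, 5 of 7 at 3 weeks and 2 at 6 weeks (7 and 4 adjusted over the list alone). Trim30a stood at 2.57 ± 0.52 and 2.14 ± 0.49 and Stat1 at 1.30 ± 0.32 at 3 weeks. Their medians were 1.30 and 0.76 (adjusted p = 4.86e-09 and 1.69e-06, and adjusted p = 0.0362 and 0.0578 with an estimated correlation). Cholesterol synthesis genes were lower, with all 14 measured below control at both times and medians of −0.71 and −0.78 (adjusted p = 9.3e-10 and 1.69e-10, and adjusted p = 0.0468 and 0.0578 with an estimated correlation). Over all genes 5 of them fell at 6 weeks, among them Hmgcs1 from 60.4 ± 20.9 to 37 ± 19.5 CPM, Hmgcr, the rate-limiting enzyme, by 0.67 ± 0.18 and Insig1 by 1.197 ± 0.30. Adjusted over the list alone, 10 and 9 were lower. Transport and gap junction genes, of which 4 of 15 are naming markers, had a median of −0.22 at 3 weeks (adjusted p = 0.0217, and adjusted p = 0.418 with an estimated correlation) and −0.17 at 6 weeks (adjusted p = 0.296). Matrix genes did not pass (adjusted p = 0.793 and 0.797). Mitochondrial transcripts had medians of −0.37 and −0.94 in these libraries (adjusted p = 0.0483 and 3e-04, and 0.81 and 0.57 with an estimated correlation). Microglia transcripts were higher as a group at 3 weeks (median 1.13, adjusted p = 0.0483, and adjusted p = 0.418 with an estimated correlation). Neuronal, granule and oligodendrocyte transcripts did not pass (lowest adjusted p = 0.259). Cluster 4 held 65.6% of astrocytes in control and 22.9% in epilepsy at 6 weeks, and cluster 6 held 28.2% and 66.0%; cluster 4 held 37.1% in epilepsy without epilepsy_6wk replicate 3, and cluster 6 17.4% in control without control_6wk replicate 3. With the mitochondrial covariate 109 genes were called at 6 weeks, 108 of them among the 291. The counts without the batch term were 84 and 91, without batch 28 19 at 3 weeks and without batch 27 15 at 6 weeks. In the fit to the libraries of the time point alone 24 genes were called at 3 weeks, and DESeq2, which shifted the median of all genes by 0.10 and 0.21, called 380 and 523.

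In oligodendrocytes 9 genes were higher and 2 lower of 9060 tested at 3 weeks, and 3 were higher and 2 lower at 6 weeks. C4b, a complement component, rose from 11 ± 9.81 to 232 ± 227 CPM at 3 weeks (4.47 ± 0.88, adjusted p = 0.0359) and from 20.1 ± 16 to 253 ± 133 CPM at 6 weeks (3.43 ± 0.60, adjusted p = 0.0347). The serine protease gene Klk6 rose from 3.53 ± 3.13 to 25.6 ± 13.6 CPM and from 5.15 ± 3.90 to 20.6 ± 12.9 CPM. At 3 weeks the cytokine gene Il33 rose from 232 ± 44.8 to 454 ± 136 CPM, the class I antigen H2-D1 from 10.2 ± 4.39 to 59.3 ± 65.4 CPM and the noncoding RNA Neat1 from 1160 ± 279 to 2520 ± 1180 CPM. At 6 weeks the Rac-inactivating gene Arhgap15 rose by 1.49 ± 0.24 and Mfge8, which tags cells for phagocytosis, fell by 2.02 ± 0.39. Another gene, 9330111N05Rik, outside the naming rule and named after its values were seen, fell by 0.67 on the log2 scale. Disease-associated oligodendrocyte genes were higher as a group at both times. Of 10 measured, 4 rose at 3 weeks and 2 at 6 weeks, and 9 and 6 when adjusted over the list alone, with medians of 1.37 and 0.69 (adjusted p = 4.2e-21 and 3.67e-11, and 0.000227 and 0.0045 with an estimated correlation). Cholesterol synthesis genes had medians of −0.32 and −0.35 over 13 genes (adjusted p = 0.000335 and 0.000802, and adjusted p = 0.367 and 0.338 with an estimated correlation). Myelin genes, of which 5 of 14 had served to name the class, did not pass (adjusted p = 0.667 and 0.77). Microglia transcripts were higher as a group at 3 weeks (median 0.75, adjusted p = 0.000335, and adjusted p = 0.102 with an estimated correlation) and not at 6 weeks (0.33). At 6 weeks mitochondrial, neuronal and astrocyte transcripts had medians of −0.75, −0.46 and −0.80 (adjusted p = 0.000802, 0.00365 and 0.00204, and 0.338, 0.338 and 0.246 with an estimated correlation). DESeq2 called 43 and 21 genes, 62.8% and 33.3% of them higher against 81.8% and 60% in the edgeR test. Without the batch term 3 and 2 genes were called, and with the mitochondrial covariate 25 at 3 weeks. EdgeR called 0 genes without batch 28 at 3 weeks (505 unadjusted) and without batch 27 at 6 weeks (665), and at 6 weeks 2 of 40 reassignments of treatment within batches, the real one included, called as many genes (highest other 40).

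In oligodendrocyte precursors (OPC) 2 genes were called at 3 weeks and 157 at 6 weeks, 148 of the latter lower, of 8188 tested. Without batch 25 edgeR called 0 at 6 weeks (271 unadjusted), and 3 of 40 reassignments, the real one included, called as many genes (highest other 549). At 6 weeks Ndst3, a heparan sulfate-modifying enzyme, rose from 6.36 ± 4.08 to 51.0 ± 24.6 CPM (3.25 ± 0.49, adjusted p = 0.00119). Aldh1a1, which makes retinoic acid, rose from 15.8 ± 10.5 to 54.4 ± 27.4 CPM and the glutamate receptor Grm8 by 1.44 ± 0.35 on the log2 scale. Resp18 fell by 2.63 ± 0.38, Mfge8 from 38.1 ± 14.4 to 14.7 ± 6.16 CPM, and Calb1, a marker of granule neurons, by 3.26 ± 0.57. At 3 weeks the interferon-induced gene Ifi27 rose from 37.7 ± 24.5 to 93.5 ± 47.3 CPM, and Inpp4b, named after its values were seen, fell from 688 ± 154 to 425 ± 130 CPM. OPC identity genes, 5 of which had served to name the class, had a median of 0.13 at 6 weeks (11 measured, 3 higher adjusted over the list alone, adjusted p = 0.0048, and adjusted p = 0.148 with an estimated correlation) and 0.04 at 3 weeks (0.474). Disease-associated oligodendrocyte genes were higher as a group in OPC at 3 weeks (7 measured, median 0.65, adjusted p = 0.0034, and adjusted p = 0.144 with an estimated correlation) and not at 6 weeks (0.972). Matrix genes, a list that holds the naming marker Vcan, did not pass (0.682 and 0.972). Microglia transcripts were higher at 3 weeks too (median 1.46, adjusted p = 0.0034, and adjusted p = 0.144 with an estimated correlation). At 6 weeks transcripts of other cells were lower as groups, namely neuronal (median −0.80, adjusted p = 4.83e-05), astrocyte (−0.47, 0.00131) and oligodendrocyte transcripts (−0.67, 0.00783), and mitochondrial transcripts had a median of −1.41 (3.74e-05). Their adjusted p was 0.148, 0.204, 0.316 and 0.285 with an estimated correlation. With the mitochondrial covariate 5 genes were called at each time, and 5 of the 157 were among those of 6 weeks. Without the batch term the 6-week count was 9, and at 3 weeks edgeR called 0 genes without control_3wk replicate 5 (426 unadjusted) and without batch 25, 28 or 29 (205 to 314), where DESeq2 on all libraries called 22.

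Microglia had 9 genes higher and 3 lower of 3793 tested at 3 weeks, and 35 higher and 15 lower at 6 weeks. The calcium channel subunit Cacna1a rose from 90.6 ± 32.2 to 450 ± 193 CPM at 3 weeks (2.26 ± 0.44, adjusted p = 0.0345) and from 134 ± 61.8 to 343 ± 177 CPM at 6 weeks. Arhgap24, a Rac regulator, rose by 2.72 ± 0.55 and 1.70 ± 0.36, Rassf3 by 1.85 ± 0.38 and 1.24 ± 0.24, and the actin regulator Wipf1 by 1.36 ± 0.28 and 0.83 ± 0.20. Tmem163, a zinc transporter, was higher in epilepsy at 3 weeks by a ratio of 26.9 (95% counting interval 4.79 to 1070; 328 UMIs against 1), and rose by 2.98 ± 0.60 at 6 weeks. Spp1, which encodes osteopontin, was higher in epilepsy at 6 weeks by a ratio of 163 (29 to 6440; 454 UMIs against 1). Anapc15 rose by 1.90 ± 0.31 and the myosin gene Myo5a by 1.40 ± 0.30 (in 3 of 4 batches) at 6 weeks. Stambpl1 and Asb2 fell at 3 weeks by 1.43 ± 0.29 and, in 3 of 4 batches, by 1.72 ± 0.40. The fructose transporter Slc2a5 fell from 192 ± 73.3 to 74.2 ± 50.1 CPM at 6 weeks, with Bank1 at −1.997 ± 0.46, the protease Htra1 at −1.90 ± 0.40 and the mitochondrial proteins Atp5d and Ndufab1 at −1.51 ± 0.37 and −1.34 ± 0.31.

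Disease-associated microglia genes were higher as a group in microglia at both times at the preset correlation (adjusted p = 1.22e-07 and 3.8e-09), but not with an estimated one (adjusted p = 0.158 and 0.129 with an estimated correlation). Of 14 measured, edgeR called 0 over all genes at 3 weeks (11 unadjusted, and 3 called by DESeq2) and 5 at 6 weeks. Adjusted over the list alone 11 and 9 were higher, and the medians were 1.93 and 1.07. Clec7a, a glucan receptor, rose from 14 ± 18.4 to 95.2 ± 87.4 CPM (in 3 of 4 batches), the growth factor Csf1 from 14.8 ± 14.5 to 93.0 ± 72.3 CPM and the lipase Lpl from 11.4 ± 9.95 to 88.1 ± 77.5 CPM (in 3 of 4 batches) at 6 weeks. Apoe, a lipid carrier, rose from 3300 ± 845 to 8570 ± 4270 CPM. Homeostatic genes, of which 4 of 14 had served to name the class, had medians of −0.37 and −0.26 (adjusted p = 0.000262 and 0.000818, and adjusted p = 0.227 and 0.224 with an estimated correlation). Selplg, a selectin ligand, stood at −0.82 ± 0.20 at 6 weeks. Interferon response genes were higher as a group at 3 weeks (median 1.19, adjusted p = 0.000313, and adjusted p = 0.158 with an estimated correlation) and not at 6 weeks (0.0898). Of 5 measured, 5 were higher at 3 weeks when adjusted over the list alone, but 0 over all genes by edgeR (5 unadjusted) and 0 by DESeq2. Complement genes did not pass (0.172 and 0.473). Mitochondrial transcripts had medians of −0.78 and −1.13 beside them (adjusted p = 1.47e-05 and 4.32e-06, and 0.257 and 0.224 with an estimated correlation). Neuronal transcripts had a median of −1.27 at 6 weeks (adjusted p = 6.83e-06, and adjusted p = 0.224 with an estimated correlation). Astrocyte and oligodendrocyte transcripts did not pass (lowest adjusted p = 0.0898). With the mitochondrial covariate edgeR called 0 genes at 3 weeks (321 unadjusted) and 8 at 6 weeks. DESeq2 without it called 94 and 164, of which 43.6% and 53.7% were higher against 75% and 70% in the edgeR test. DESeq2's scaling moved the median of all genes by −0.47 and −0.39. RLE size factors gave 24 calls at 3 weeks with 58.3% higher, and 3 genes were called at 6 weeks without the batch term and 2 without batch 27 or 29. At 3 weeks edgeR called 0 without batch 25, 28, 29, 40-3 or 40-6 (299 to 551 unadjusted), and at 6 weeks 2 of 40 reassignments, the real one included, called as many genes (highest other 376).

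**Figure D4:**
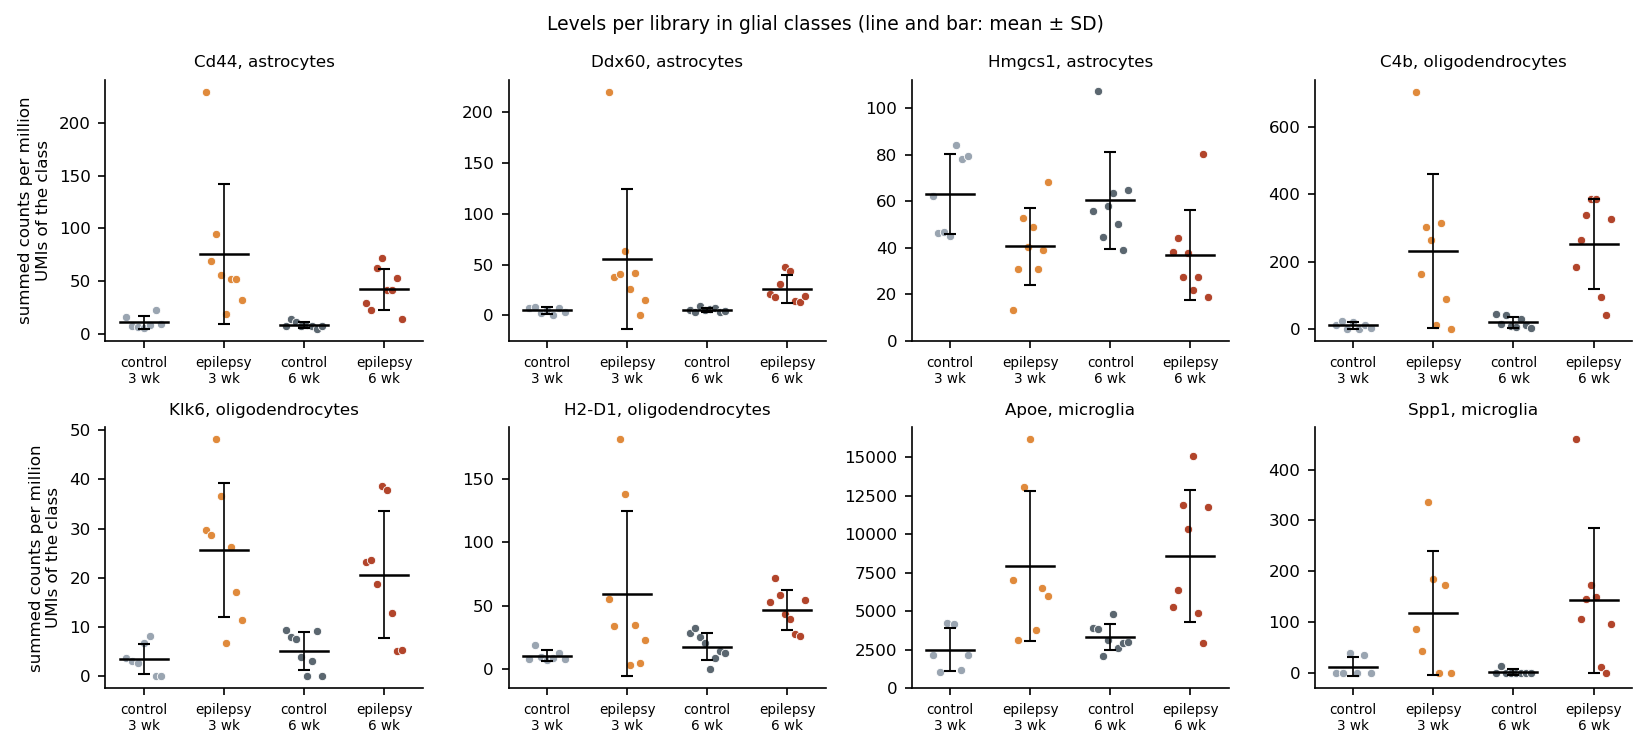
Level of 8 genes in astrocytes, oligodendrocytes and microglia in CPM, with each library as a point and a line and bar for mean ± SD, for control and epilepsy at 3 and 6 weeks. C4b in oligodendrocytes averaged 232 CPM in epilepsy against 11 CPM in control at 3 weeks.

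**Figure D5:**
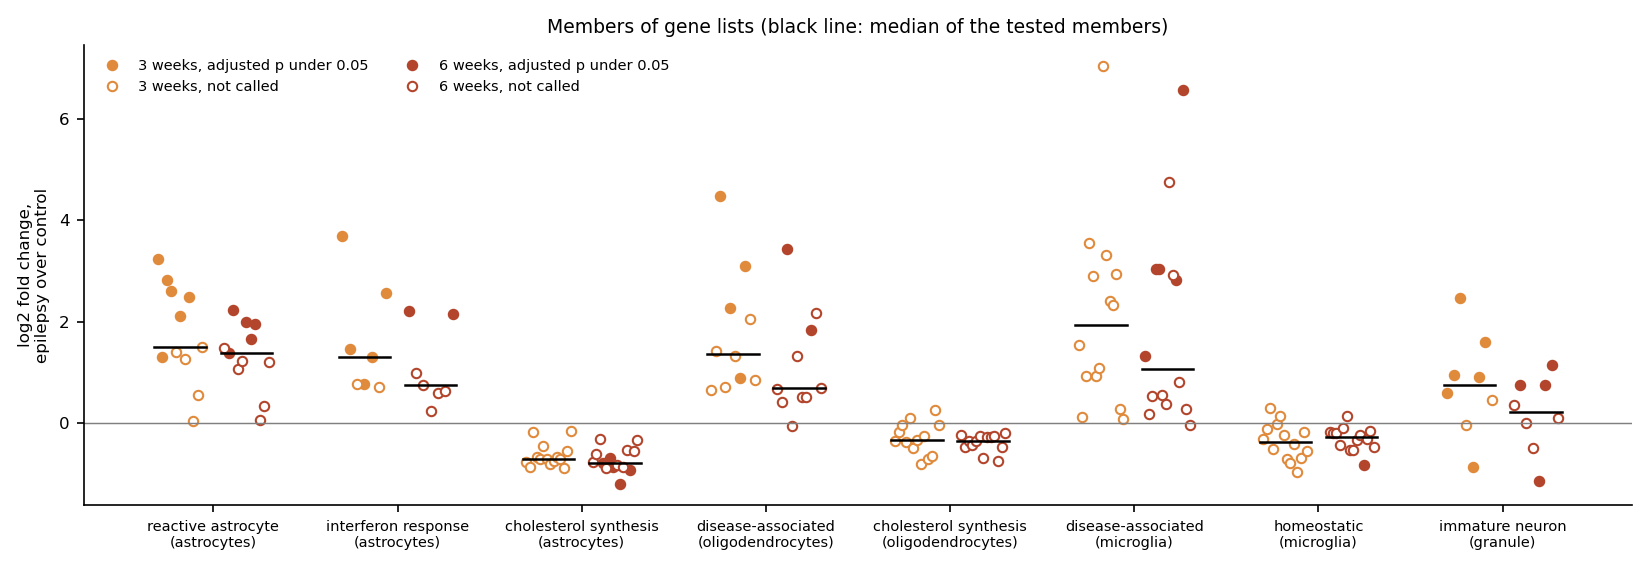
Log2 fold change of epilepsy over control for each measured member of 8 gene lists in the class named, at 3 and 6 weeks, with filled points for members with an adjusted p under 0.05 over all genes and a black line at the list's median. Reactive astrocyte genes had medians of 1.51 and 1.39.

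The same genes were called at both times in granule neurons more often than independent lists would give. There, 544 genes were higher at both times (75.8 for independent lists of these sizes) and 556 lower (79.2), and 0 genes were called in opposite directions by edgeR or DESeq2; without the filter on low counts 54 were, and without batch 27, 29 and 40-3 3, 1 and 2. Astrocytes shared 89 higher and 16 lower genes (2.9 and 0.6 for independent lists), CA1 neurons 29 and 26 (1.0 and 0.9) and microglia 6 higher genes (0.1). Of the genes called at 3 weeks, 1331 of 1371 in granule neurons, 80 of 82 in CA1 and 223 of 224 in astrocytes had the same sign at 6 weeks. The test of the difference, 6 minus 3 weeks, called Gm32647 and Cd63 in CA1 neurons and Resp18 in OPC. In the other 6 main classes edgeR called 0 genes for that difference, with 1296 at an unadjusted p under 0.05 in granule neurons, 1002 in CA3, 1065 in GABAergic neurons, 287 in astrocytes, 354 in oligodendrocytes and 104 in microglia. Chance alone gives 0.05 of the genes tested, so such counts show no change by themselves. DESeq2 called 12 in GABAergic neurons and 0 in the other 5. Without the filter on low counts 5 of these classes had 23 to 829 calls for the difference. With a batch or control_3wk replicate 5 left out edgeR called at most 1 gene for it in granule neurons and 2 in GABAergic neurons. Median, mean and test differed in sign for 36 of the 166 lists tested, and 0 of those 36 had passed.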

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

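The tests with a mitochondrial covariate, without control_3wk replicate 5, without cluster 19 and with cluster 0 alone were chosen after the results they bear on were seen, as was the comparison of the mitochondrial shares of single libraries in batch 40-6; the other tests in this part were set before.

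The test of the effect at 6 minus 3 weeks (edgeR quasi-likelihood, Benjamini-Hochberg adjusted) passed for 3 genes. In CA1 neurons Gm32647, an uncharacterised gene model, had a difference of 0.875 ± 0.155 (adjusted p = 0.0326), from a log2 fold change of 0.887 at 3 weeks to 1.762 at 6 weeks. It passed in 4 of 15 alternatives, with adjusted p from 1.27e-06 to 1. Cd63, which encodes a tetraspanin, had a difference of −8.902 ± 1.379 in CA1 (adjusted p = 0.0196) and passed in 7 of 15 alternatives, with adjusted p from 2.17e-44 to 1. Epilepsy held 1 UMI of it over all libraries at 6 weeks and control 412, a ratio of 325 (95% counting interval 57.9 to 12,900), so the fitted size depends on near-zero counts and is no bound. In OPC Resp18, a secretory protein gene, had a difference of −2.89 ± 0.561 (adjusted p = 0.0386) and passed in 6 of 11 alternatives, with adjusted p from 0.00148 to 0.719.

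Some libraries stood apart from the rest of their group, judged by the gap to the nearest library as a share of the group's range (Dixon's ratio). Of 176 groups of values examined 22 exceeded the critical value, where chance gives about 1 in 20; these were 12 of 96 groups for genes, 7 of 64 for class shares and 3 of 16 for library measures. Control_3wk replicate 6 had 11.52% endothelial nuclei against at most 2.46% in the others (ratio 0.824) and 5.15% fibroblasts against at most 1.58% (0.71). Control_6wk replicate 6 had 22.7% oligodendrocytes against at most 11.2% (0.592). Epilepsy_3wk replicate 1 had 36.6% microglia against at most 12.4% (0.67). At 6 weeks in epilepsy, replicate 3 had 24.0% astrocytes against at most 10.05% (0.662), replicate 8 had 6.38% subicular neurons against at most 4.02% (0.562) and replicate 7 had 0.188% mossy cells against at most 0.074% (0.606). The percent of mitochondrial UMIs was 1.095 in control_3wk replicate 3 against at most 0.515 (0.581) and 1.646 in epilepsy_6wk replicate 6 against at most 0.7411 (0.583). Unnamed nuclei made up 51.98% of epilepsy_6wk replicate 8 against at most 23.95% (0.647).

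Levels of named genes gave the other 12, in CPM. In epilepsy_3wk replicate 1, astrocytes held Col4a6 at 114.7 against at most 41.83 (ratio 0.674) and Ddx60 at 220.2 against at most 62.92 (0.714), OPC held Ndst3 at 153.1 against at most 60.36 (0.606), and CA1 neurons held Tmtc2 at 18.9 against at least 33.9 (0.678). That library stood apart 5 times in all, and control_3wk replicate 6 3 times, the last with Ranbp3l in astrocytes at 116.1 against at least 202.2 (0.589). Microglia of control_6wk replicate 8 held Htra1 at 378.9 against at most 147.6 (0.61). Spp1 in microglia was 14.47 in control_6wk replicate 2 and 0 in the others (1), and 459.8 in epilepsy_6wk replicate 1 against at most 173.1 (0.624). Mfge8 in oligodendrocytes was 69.93 in control_3wk replicate 3 against at most 26.28 (0.654), and Ndst3 in OPC 78.07 in control_3wk replicate 4 against at most 32.51 (0.584). Scrg1 in GABAergic neurons was 11.52 in epilepsy_3wk replicate 3 against at most 3.021 (0.738), and Slc6a1 in CA3 neurons 3.539 in epilepsy_6wk replicate 4 against at most 1.455 (0.589).

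At 6 weeks mitochondrial transcripts and transcripts of other cells were lower in epilepsy in most classes, so the 6-week calls may come from a different amount of cytoplasmic or free RNA between the libraries. Batch 40-6 was taken in advance to have like mitochondrial shares, and in it genes higher and lower in epilepsy kept 71.7% and 56.8% of their median log2 fold change in granule neurons, 55.9% and 52.3% in CA1, 59.7% and 69% in CA3 and 92.4% and 17.8% in GABAergic neurons; but the share of control_6wk replicate 8 was 4.92, 8.14, 17 and 3.21 times the epilepsy mean, and that of replicate 7, the 1 other control library there, 0.876, 0.517, 0.16 and 0.606 times, so the bounds set in advance are not applied, and these sets cannot be told apart from that explanation by 1 library; against replicate 7 alone the higher and lower genes kept 68.7% and 49.9% in granule, 57.3% and 37.6% in CA1, 56.4% and 39.5% in CA3 and 67.1% and 11.7% in GABAergic neurons. With the mitochondrial share as a covariate 62.4% of the 3142 granule genes were called again in their direction (median change 0.57 against 0.66, median SE 0.17 against 0.15), which argues against a trend with that share as their whole cause; 11.9% were in CA1, 22.8% in CA3 and 16.4% in GABAergic neurons, where their median changes stood at 0.50 against 0.63, 0.69 against 0.70 and 0.90 against 1.15 and the trend stays open, since the share itself differs with treatment. In other splits lower GABAergic genes kept up to 17.2%. In astrocytes the control shares were 0.703 and 1.08 times the epilepsy mean. Genes lower in them kept 7.1% (highest other split 10.1%), as the explanation needs. A weak effect in this batch would also keep little, so RNA background stays a hypothesis. Genes higher in astrocytes kept 32.9% (highest other split 24.6%), between the bounds. Genes lower in OPC kept −16.5%, with control shares 0.347 and 1.82 times the epilepsy mean. Genes higher in microglia kept 24.4% (highest other split 84.5%) and those lower −31.2%. RNA background stays open for these.

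The granule calls could reflect which clusters make up the class, since cluster 19 is found mostly in epilepsy at 3 weeks (29.1% of granule nuclei, 18.8% without epilepsy_3wk replicate 4) and cluster 0 holds most granule nuclei in epilepsy at 6 weeks. Without cluster 19, 87% of the 1371 genes called at 3 weeks were called again in the same direction, which argues against that cluster as their source. In cluster 0 alone 43.5% of the 3142 genes called at 6 weeks were called again, between the bounds set in advance, and 2842 of the 3142 had the same sign. That explanation therefore cannot be told apart from a change within granule neurons at 6 weeks, because cluster 0 alone also has fewer nuclei and fewer calls. The treatment itself, and a change of granule neurons that moves nuclei between clusters, stay open as untested.

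The disease-associated genes higher in oligodendrocytes at 3 weeks could be RNA of neighbouring glia in oligodendrocyte nuclei. Against astrocytes as the source, 4 of the 4 called genes had a higher level in oligodendrocytes than in astrocytes in at least 6 of 8 epilepsy libraries, with Klk6 at 25.6 against 1.61 CPM, C4b at 232 against 118, H2-D1 at 59.3 against 43.3 and Il33 at 454 against 28. Against microglia as the source, 3 of the 4 were higher in oligodendrocytes; H2-D1 was not, at 59.3 against 312 CPM and higher in 1 of 8 libraries, so for H2-D1 microglial RNA stays open. A candidate explanation is a response of oligodendrocytes to the treatment, a hypothesis found and examined on the same libraries.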

How the results depend on the processing

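The fits with the percent of mitochondrial UMIs as a covariate, without control_3wk replicate 5 and with cluster 0 alone, the shares over all nuclei or without epilepsy_3wk replicate 1 or epilepsy_6wk replicate 7, and the clustering without the differing markers were chosen after the results were seen, as were the counts of genes shared between 3 and 6 weeks under each alternative.

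Of the 243 named genes, 97 kept their direction and stayed past the threshold in every alternative in which they were fitted, and of 166 lists 120 kept their side of the threshold. By alternative, 236 of 241 named genes kept their call with DESeq2, 233 of 243 with RLE size factors, 235 without the filter on low counts, 225 with at least 50 nuclei per library, 157 of 184 with the libraries of the time point alone, 143 without the batch term, 178 with the mitochondrial covariate and 239 without control_3wk replicate 5. With a batch left out it was from 153 of 233 (batch 25), 174 of 233 (29) and 171 of 226 (27) to 221 of 243 (40-3). Among named genes and these alternatives 1 reversed: Sst in CA1 at 6 weeks had a log2 fold change of −4.47, and 0.19 with the mitochondrial covariate, and the cause was not tested. Depth limits which genes pass the filter on low counts, 3793 in microglia against 13,884 in granule neurons. At 3 weeks the simulation recovered 17.7% of 2-fold and 80% of 4-fold changes in microglia against 76.1% and 95.2% in granule neurons, so a low count there does not show that few genes changed; whether depth, the number of libraries or their spread sets this was not tested. No paired analysis was possible because the labels give no replicate numbers, so the model used batches. Subtypes of microglia were planned and not run, and mossy cells had too few libraries for a test of genes. Where edgeR or DESeq2 called 0 genes under an alternative named below, between 55 and 1644 genes had an unadjusted p under 0.05. The cause of the changes listed here was not tested, unless fewer samples or more genes tested come with the alternative itself.

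Without the filter on low counts more genes were tested and more called. The counts at 3 and 6 weeks were 463 and 1741 in CA1, 109 and 1135 in CA3, 182 and 1139 in GABAergic neurons, 815 and 1330 in astrocytes, 162 and 561 in oligodendrocytes, 26 and 426 in OPC and 166 and 333 in microglia. That setting moved the median of all genes in microglia by 0.38 and 0.10. The difference between the times then had 829 calls in granule neurons, 755 in CA1, 471 in CA3, 570 in GABAergic neurons, 23 in astrocytes, 47 in oligodendrocytes and 22 in OPC. Genes shared by both times numbered 225 in CA1, 49 in CA3, 60 in GABAergic neurons, 461 in astrocytes, 75 in oligodendrocytes, 5 in OPC and 89 in microglia.

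Without the batch term fewer genes were called in the classes and times given next: 766 and 1632 in granule neurons, 3 and 148 in CA1, 0 and 7 in GABAergic neurons, 84 and 91 in astrocytes, 3 and 2 in oligodendrocytes and 0 and 9 in OPC. At 6 weeks CA3 had 28 and microglia 3, while microglia at 3 weeks had 15 against 12 with it. The difference between the times had 0 calls in CA1 and in OPC. Shared genes numbered 665 in granule neurons, 3 in CA1, 33 in astrocytes, 1 in microglia, 1 in oligodendrocytes and 0 in GABAergic neurons. In GABAergic neurons 2 lists passed at 3 weeks in place of 1.

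The libraries of the time point alone, a smaller fit, gave at 3 weeks 875 calls in granule neurons, 13 in CA1, 2 in CA3, 24 in astrocytes, 2 in oligodendrocytes and 0 in GABAergic neurons, OPC and microglia. At 6 weeks it gave 1014 in CA1, 419 in GABAergic neurons and 51 in OPC. Shared genes numbered 9 in CA1, 1 in CA3, 13 in astrocytes and 0 in GABAergic neurons, oligodendrocytes and microglia.

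The mitochondrial covariate left at 6 weeks 85 calls in CA1, 90 in CA3, 34 in GABAergic neurons, 109 in astrocytes, 5 in OPC and 8 in microglia. At 3 weeks it gave 25 in oligodendrocytes, 4 in GABAergic neurons, 5 in OPC and 0 in microglia. For the difference between the times it gave 1 in granule neurons, 1 in CA1 and 0 in OPC. Shared genes were 32 in CA1, 53 in astrocytes and 0 in microglia.

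DESeq2 called 259 genes at 3 weeks in CA1, 1 in CA3, 10 and 302 in GABAergic neurons, 380 and 523 in astrocytes, 43 and 21 in oligodendrocytes, 22 and 240 in OPC and 94 and 164 in microglia. It called 6 genes for the difference between the times in CA1 and 12 in GABAergic neurons. Shared genes were 143 in CA1, 1 in CA3, 5 in GABAergic neurons, 169 in astrocytes, 7 in oligodendrocytes, 3 in OPC and 27 in microglia, and its scaling moved the median of all genes in oligodendrocytes by −0.16 and −0.21. RLE size factors gave 24 calls in microglia and 0 in OPC at 3 weeks, and 1 for the difference in CA1. A minimum of 50 nuclei gave 326 calls in GABAergic neurons at 6 weeks, 9 in OPC and 2 in CA3 at 3 weeks, and for the difference 1 in CA1, 1 in GABAergic neurons and 0 in OPC. With it 2 genes were shared in CA3, 3 in OPC and 2 in microglia. Cluster 0 alone gave 1454 calls in granule neurons at 6 weeks.

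Leaving out a batch, or control_3wk replicate 5, also takes away samples. At 3 weeks the calls ranged from 675 (without batch 28) to 1392 in granule neurons, from 8 (28) to 80 in CA1, from 0 to 2 (27) in CA3, from 0 (28) to 10 (41) in GABAergic neurons, from 19 (28) to 521 (41) in astrocytes, from 0 (28) to 16 in oligodendrocytes, from 0 (25) to 7 (41) in OPC and from 0 (25) to 14 in microglia. At 6 weeks they ranged from 1623 (25) to 3568 (without the replicate) in granule neurons, from 135 (25) to 1073 (40-3) in CA1, from 53 (27) to 639 (40-3) in CA3, from 8 (25) to 342 (without the replicate) in GABAergic neurons, from 15 (27) to 409 in astrocytes, from 0 (27) to 10 (40-6) in oligodendrocytes, from 0 (25) to 264 (40-6) in OPC and from 2 (27) to 112 (28) in microglia. For the difference between the times the ranges were 0 to 1 in granule neurons, 0 to 5 in CA1, 0 to 2 in GABAergic neurons and 0 to 1 in OPC. Shared genes ranged from 606 to 1120 in granule neurons, 7 to 48 in CA1, 0 to 2 in CA3, 0 to 4 in GABAergic neurons, 6 to 189 in astrocytes, 0 to 3 in oligodendrocytes, 0 to 1 in OPC and 0 to 6 in microglia.

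Shares depended on the batches as strata. Without strata the adjusted exact p was 0.063 for astrocytes, mossy cells and oligodendrocytes and 0.1459 for microglia at 6 weeks, and 0.0945 for immature granule neurons at 3 weeks. Over nuclei other than granule neurons oligodendrocytes at 3 weeks had an adjusted exact p of 0.0463. Over all nuclei, unnamed ones included, microglia and oligodendrocytes at 3 weeks had 0.0247 and 0.0123. Clustering without the differing markers gave 0.0802 for immature granule neurons at 3 weeks. With a batch left out, fewer reassignments remain, and the adjusted exact p ranged from 0.0593 to 0.0988 for astrocytes, microglia, mossy cells and oligodendrocytes at 6 weeks; without epilepsy_6wk replicate 7 it was 0.0395 for oligodendrocytes and 0.0247 for the others. Astrocytes at 3 weeks passed without epilepsy_3wk replicate 1 (0.0494) and had up to 0.2016 with a batch left out. With a batch left out it started at 0.0329 at 3 weeks, and reached 0.1152 for immature granule neurons, 0.4055 for CA1, 0.8466 for fibroblasts, 0.2531 for microglia and 0.2963 for oligodendrocytes. All lists called in neurons other than granule neurons, in OPC and in microglia were lost with an estimated correlation, leaving 0 lists called by camera in CA1 at 6 weeks and, at both times, in CA3, GABAergic neurons, OPC and microglia. With it 1 list was left in granule neurons at 3 weeks and 0 at 6 weeks, 3 and 1 in astrocytes and 1 and 1 in oligodendrocytes.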

Other observations

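The regroupings of the granule and microglia libraries were chosen after the counts they bear on were seen, as were the fit with the mitochondrial covariate and that without control_3wk replicate 5; the other tests in this part were planned.

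Beside the 8 main classes, immature granule neurons changed most: 102 genes were higher and 29 lower at 3 weeks and 175 higher and 168 lower at 6 weeks, of 2829 tested. With the mitochondrial covariate 129 and 120 genes were called in that class, 113 and 111 of them among the former, and the counts ranged from 1 (without batch 28) to 162 at 3 weeks and from 37 (without batch 25) to 403 at 6 weeks when a batch was left out. Subicular neurons had 1 gene higher and 20 lower of 10,804 at 6 weeks, and CA2 neurons 6 higher and 11 lower of 7505; without control_3wk replicate 5 these counts were 50 and 36, and without batch 25 edgeR called 0 in both (533 and 565 at an unadjusted p under 0.05). In endothelial cells the ceramidase gene Acer2 was called at 6 weeks, at 285 ± 113 CPM in epilepsy against 77.3 ± 30.6 in control (log2 fold change 1.79 ± 0.32, edgeR adjusted p = 0.0122). In fibroblasts Rassf8 was called at 6 weeks, at 206 ± 67.9 against 86.4 ± 62.8 CPM (1.25 ± 0.23, edgeR adjusted p = 0.0444). Acer2 was not called without batch 25, 35 or 40-6. Rassf8 was not called with RLE size factors, without the batch term, with the mitochondrial covariate, with at least 50 nuclei or without batch 25, 27, 29, 35, 40-3 or 40-6. Both were named after their values were seen.

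In the remaining tests of these classes edgeR, the tool run for them, called 0 genes on the full set of libraries with the filter on low counts. At 3 weeks this held in CA2 (345 unadjusted), subicular (646), endothelial (92), fibroblast (69), Cajal-Retzius (96) and pericyte nuclei (56), and at 6 weeks in Cajal-Retzius (259) and pericyte nuclei (35). With other settings Cajal-Retzius nuclei at 6 weeks had up to 18 calls (without batch 40-6; 16 without the filter) and CA2 at 3 weeks up to 3, and without the filter there were 102 in subicular and 2 in fibroblast nuclei at 3 weeks and 4 in pericyte nuclei at 6 weeks. The difference between the times had 0 calls in all 7, with 127 at an unadjusted p under 0.05 in immature granule neurons, 556 in CA2, 919 in subicular, 120 in Cajal-Retzius, 22 in endothelial, 96 in fibroblast and 39 in pericyte nuclei. Without the filter it had 455 calls in subicular, 45 in CA2, 2 in immature granule, 2 in fibroblast and 1 in Cajal-Retzius nuclei, and CA2 had 2 without batch 40-3 and 1 without control_3wk replicate 5. Of the unnamed clusters none differed in share between epilepsy and control (lowest adjusted p = 0.296, exact permutation test). Cluster 3 made up 1.03% ± 1.09 of nuclei in epilepsy and 19.5% ± 31.9 in control at 3 weeks (8.08% ± 11.6 without control_3wk replicate 5), and was most of that library.

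Treatment was reassigned within batches in 40 splits of the libraries, the real one included (36 for immature granule neurons), and the genes called were counted again. For the counts given next only the real split, 1 of 40 (1 of 36 for immature granule neurons), called as many genes. That is the smallest share these splits can give. It was not adjusted over the counts examined, so it does not by itself exclude chance. Granule neurons had 1371 and 3142 calls at 3 and 6 weeks against at most 1 and 46 in the other splits, CA1 82 and 672 against 0 and 6, astrocytes 224 and 291 against 22 and 0, and immature granule neurons 131 and 343 against 0 and 0. The same held for CA3 (359 against 1) and GABAergic neurons (165 against 10) at 6 weeks, for oligodendrocytes (11 against 1) and microglia (12 against 0) at 3 weeks, and for CA2 (17 against 1) and subicular nuclei (21 against 0) at 6 weeks. The real split was also the highest, in 1 of 40, for GABAergic neurons (1 gene against 0) and OPC (2 against 1) at 3 weeks, endothelial nuclei at 6 weeks (1 against 0) and the difference in CA1 (2 against 1). These exceed the highest other split by 1 gene, so chance stays open for them too. With a batch left out edgeR called 0 in each (588, 242, 62 and 654 unadjusted without batch 28, 25, 25 and 25), and also in several of the larger counts above: oligodendrocytes at 3 weeks without batch 28 (505), microglia at 3 weeks without batch 25, 28, 29, 40-3 or 40-6 (299 to 551), and CA2 and subicular nuclei at 6 weeks without batch 25 (565 and 533).

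Chance could not be excluded for the remaining counts either. As many genes as in the real split were called in 2 splits for oligodendrocytes at 6 weeks (5 calls, highest other 40), in 3 for OPC at 6 weeks (157, highest other 549), in 2 for the difference in OPC (1, highest other 15), in 2 for microglia at 6 weeks (50, highest other 376) and in 2 for fibroblasts at 6 weeks (1, highest other 1). In oligodendrocytes, OPC and microglia another split had several times the real count, and the cause was not tested. For counts of 0 all 40 splits were as large by construction. The highest other counts there were 99 in granule neurons, 65 in astrocytes, 33 in microglia, 1 in GABAergic neurons and 0 in CA3 and oligodendrocytes for the difference between the times. They were 0 for CA3, CA2, endothelial and fibroblast nuclei and 1 for subicular, Cajal-Retzius and pericyte nuclei at 3 weeks, and 1 for Cajal-Retzius and pericyte nuclei at 6 weeks.

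The number of lists called at the preset correlation did not exceed that of other splits in any main class. At 3 and 6 weeks 21 and 21 splits gave as many in granule neurons (2 and 3 lists, highest others 7 and 5), 40 and 6 in CA1 (0 and 6, highest others 6 and 6), 33 and 18 in CA3 (1 and 2; 5 and 5) and 24 and 19 in GABAergic neurons (1 and 3; 6 and 7). In glia they were 9 and 13 in astrocytes (6 and 4 lists, highest others 7 and 7), 20 and 3 in oligodendrocytes (3 and 5; 6 and 6), 27 and 4 in OPC (2 and 5; 4 and 6) and 11 and 12 in microglia (4 and 4; 6 and 6). So chance is not excluded for the number of lists.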
